A study of Homo sapiens with 24 samples.

How the data were processed

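RNA from 2 human liver cancer cell lines, HepG2 and Huh7, was studied by m5C-MeRIP-seq, with a control hairpin (sh-NC) or a hairpin against ALYREF (sh-ALYREF). Each of the 4 combinations had 3 replicates, each with an input and an IP library, so 24 samples formed 8 groups. Per the labels, total RNA was cut to fragments of about 200 nt, enriched with an m5C kit, made into libraries with a low-input whole-RNA kit, and sequenced on a NovaSeq. The submitters' notes name cutadapt 1.9.3, HISAT2 2.0.4, STAR, edgeR and the genome build hg38, with no role or order.

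The tables deposited for genes, lncRNAs and circRNAs hold counts for the 12 input libraries: reads per gene, reads per lncRNA transcript and back-splice junction reads per circRNA. Per the file headers, further columns hold log2 CPM by edgeR, and these were not used. In the deposited peak lists, 1 per IP replicate and RNA class, each peak has a fold enrichment, which is a ratio of IP over background reads by the peak caller. The score in the deposited lists is minus 10 times the log10 of the caller's p, and the FDR there is a percent. Peak names are those of MACS; how the caller used the input is not stated. The sample columns were matched to the labels by line, hairpin and replicate number, reading G2 as HepG2, V as sh-NC and SH as sh-ALYREF.

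The gene table held 16838 genes, and that for lncRNAs 202294 lines, 1 per associated gene, which were collapsed to 50586 transcripts. There were 18630 circRNAs. Gene reads ran from 15514914 to 24842908 per library, lncRNA reads from 887011 to 1421352, and circRNA junction reads from 7409 to 16791. After filtering, 13642 genes, 21002 lncRNA transcripts and 2547 circRNAs were tested, with biological coefficients of variation of 0.118, 0.489 and 0.9. A tested lncRNA transcript had a median of 17.25 reads and a tested circRNA a median of 1.33. Of the lncRNA transcripts, 12985 overlap exons of a coding gene on the same strand, so their reads can come from its mRNA.

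Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr (for circRNAs at least 2 junction reads in at least 3 libraries), and a quasi-likelihood fit with a mean for each of the 4 input groups. The contrasts were sh-ALYREF against sh-NC in HepG2, in Huh7, as the mean of both lines, and as a difference (HepG2 effect minus Huh7 effect). P values were adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold, and all tests were two-sided. The SE of a log2 fold change was its size over the square root of F. Log2 CPM for principal components used a prior count of 2. Agreement between lines was measured by correlation over genes, and overlaps of called genes by Fisher's exact test. Ratios of pooled reads were given with Clopper-Pearson intervals.

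A set of 28 gene lists, written from general knowledge before the data were examined, was tested with camera of limma 3.58.1 (preset correlation 0.01), again with the correlation estimated for each list, and with fry. They cover TREX and mRNA export, m5C writers, erasers and readers, EGFR and STAT3 signalling, cholesterol synthesis, fatty acid and triglyceride metabolism, secreted liver proteins, liver enzymes and transporters, hepatocyte transcription factors, and fetal liver and hepatocellular carcinoma markers. They also cover ATF4 and unfolded protein response, heat shock, hypoxia and glycolysis, p53, interferon, NF-kB and inflammation, immediate early genes, Wnt and beta-catenin, apoptosis, S phase, G2 and mitosis, and replication-dependent histones. The remaining lists are cytoplasmic ribosomal proteins, ribosome biogenesis and MYC targets, splicing factors and nuclear RNA-binding proteins, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, mesenchymal and migration genes, and fibroblast, endothelial and leukocyte markers. KEGG pathways were added after the data were seen.

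Genes were named by a rule set before the data were examined. ALYREF, EGFR and STAT3 were always named. For each contrast, the 10 largest rises and 10 largest falls were taken among called genes in the upper part of the level distribution (above the median) whose sh-ALYREF libraries all lay on one side of the sh-NC libraries, in both lines for the mean and in at least 1 line for the difference. From each list that passed or had at least 3 called members, the 4 called members with the smallest adjusted p were eligible. For lncRNAs, the 3 largest rises and falls under the same conditions were named, and for circRNAs, with none called, the 5 with the smallest p. For peaks, up to 10 regions lost or gained at the same place in both lines were eligible by their smallest enrichment. Y-linked genes and XIST were left out of all named genes and figures.

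Peaks were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Overlapping peaks of a line were merged into regions. The plan asked for overlap on the same strand, but the mRNA lists give no strand, so strand was ignored. Numbers of peaks and their shares by place were compared by exact permutation of the list labels, within each line or within both at once, where 3 against 3 gives a smallest p of 0.1 and both lines 0.005. For the shares, 213542 of 229750 mRNA peaks were placed on GRCh38 transcript models of GENCODE 44. Expression of genes with a lost or gained region was compared with genes of like level that had a peak in all 6 lists, by 10000 draws. Since the IP depth is not known, lists of different length may differ in depth, and each line was also tested with the same number of strongest peaks per list.

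The methods were tested on simulated data of the same depth. In HepG2, 65.2%, 77.6% and 89.2% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, for lncRNA transcripts 1.61%, 8.77% and 38.5%, and for circRNAs 0%, 0% and 0%. Alternatives were DESeq2 1.42.0, other size factors, no filter, a 2-fold minimum, each line fitted alone, a replicate block, leaving out each library in turn, peaks with a score of at least 70, an overlap of at least 0.5 of both peaks, and equal lists. Chosen after the data were seen were library totals without TMM, an offset for GC content and length (mgcv 1.9.3), subtraction of each library's share of the other line's signal, and, for the lists and the agreement between lines, other size factors, no filter (agreement alone) and leaving out libraries. The main fits did not pair libraries by replicate number. Within each line, the residual of each sh-NC input library correlated more with an sh-ALYREF library of another number than with that of its own. These correlations were small (own number -0.082 to -0.013, highest other number 0.0423 to 0.0879), so they do not settle whether the numbers pair the libraries. IP libraries were not checked.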

Results

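RNA 5-methylcytosine (m5C) and gene expression were measured by m5C-MeRIP-seq in HepG2 and Huh7, both human liver cancer cell lines. This assay sequences RNA fragments pulled down with an antibody against m5C (IP) beside the same RNA before the pull-down (input). Each line carried either a control short hairpin RNA (sh-NC) or one against ALYREF (sh-ALYREF), an mRNA export adaptor that also binds m5C. The 24 samples formed 8 groups of 3, and 12 were input and 12 were IP libraries. The labels give ALYREF deficiency and the role of ALYREF in RNA m5C modification as the subject of the study. Input libraries held 15514914 to 24842908 gene reads, 887011 to 1421352 lncRNA reads and 7409 to 16791 circRNA junction reads. The IP data were deposited as 1 peak list per replicate, and the read depth of the IP libraries is not known. On the first principal component, which held 94.8% of the variance of log2 CPM (read counts scaled to the library total, written CPM throughout), the lines separated, and on the next component, with 2.06%, the sh-NC and sh-ALYREF libraries of Huh7 did.

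The first question was how far the hairpin lowered ALYREF RNA. ALYREF (ENSG00000183684, GRCh38 chromosome 17, 81887835 to 81891587) stood at 29.3 ± 3.03 CPM in HepG2 sh-NC and 22.7 ± 3.42 CPM in HepG2 sh-ALYREF (SD, n = 3). This log2 difference of -0.37 (SE 0.15) did not pass the edgeR test in HepG2 (adjusted p = 0.113), although all 3 sh-ALYREF libraries lay below all 3 sh-NC libraries. In Huh7, ALYREF fell from 13.5 ± 0.68 to 9.56 ± 1.55 CPM (SD, n = 3), by 0.50 on the log2 scale (SE 0.159, adjusted p = 0.0196). The Huh7 call ended without sh-ALYREF replicate 3 (log2 difference -0.39) and without sh-NC replicate 2 (-0.46). Averaged over both lines, ALYREF fell by 0.43 on the log2 scale (SE 0.109, adjusted p = 0.00465), a 1.35-fold decrease, and the effects in the lines did not differ detectably (difference 0.14, SE 0.218, adjusted p = 0.731). This difference moved with single libraries, to 0.02 without Huh7 sh-ALYREF replicate 3, 0.05 without HepG2 sh-ALYREF replicate 2 and 0.07 without HepG2 sh-NC replicate 3. It was 0.21 without HepG2 sh-NC replicate 2, 0.25 without HepG2 sh-ALYREF replicate 1 and 0.26 without Huh7 sh-ALYREF replicate 2. EGFR, the epidermal growth factor receptor (ENSG00000146648, chromosome 7, 55019017 to 55211628), rose in both lines. Its level went from 12.4 ± 2.73 to 19.7 ± 1.43 CPM in HepG2 (log2 0.67, SE 0.0976, adjusted p = 2.74e-05) and from 508 ± 16.3 to 671 ± 2.85 CPM in Huh7 (log2 0.40, SE 0.0619, adjusted p = 2.16e-05). STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388442), a transcription factor of cytokine signalling, rose in Huh7 (log2 0.31, SE 0.0602, adjusted p = 2.86e-04) and stood 0.15 higher in HepG2 (SE 0.058, adjusted p = 0.099). The HepG2 value of STAT3 passed with other size factors (0.18) and, nearly unchanged, in a fit of the 6 HepG2 libraries alone (0.15). The difference between the lines did not pass for EGFR (0.27, SE 0.116, adjusted p = 0.109) or STAT3 (-0.17, adjusted p = 0.178); that of EGFR passed without HepG2 sh-NC replicate 1 (0.45) and was 0.13 without HepG2 sh-NC replicate 2, and that of STAT3 was -0.11 without Huh7 sh-ALYREF replicate 1.

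**Figure D1:**
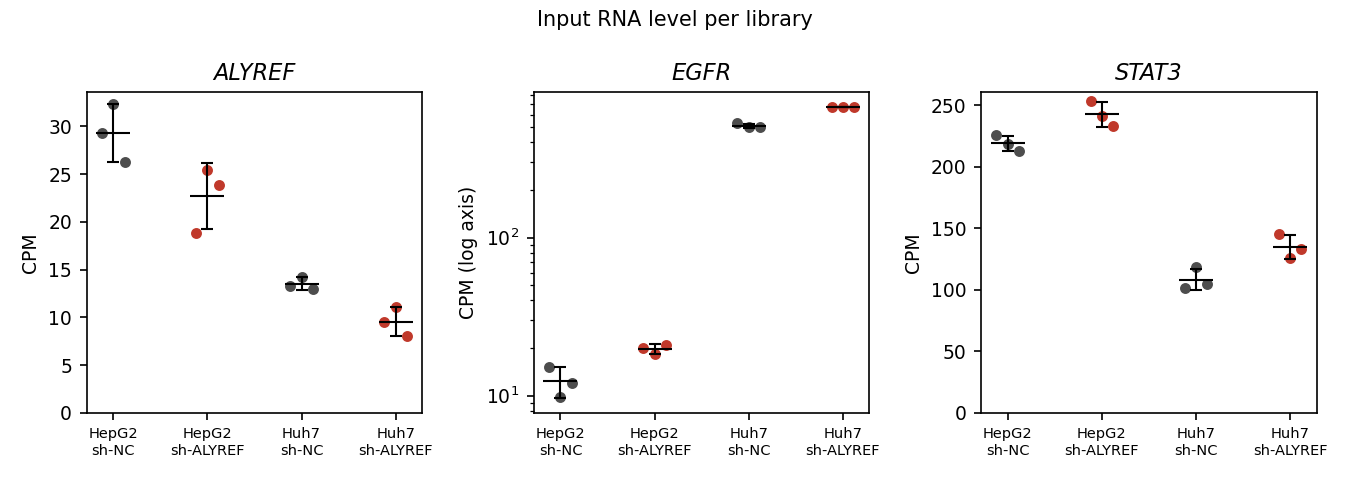
Input level (CPM) of ALYREF, EGFR and STAT3 in each library, with points for replicates, a line for the mean and bars for the SD (n = 3); the EGFR axis is logarithmic. ALYREF means were 29.3 and 22.7 CPM in HepG2 and 13.5 and 9.56 CPM in Huh7, and EGFR means were 12.4 and 19.7 CPM in HepG2 and 508 and 671 CPM in Huh7.

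In HepG2 with sh-ALYREF, genes of cholesterol synthesis and of secreted liver proteins rose. Genes of the ATF4 and unfolded protein response, of ribosome biogenesis, and of hypoxia and glycolysis fell. The test called 1767 of 13642 genes, of which 1019 rose and 748 fell. The balance of directions depended on the scaling: 1451 rose and 695 fell with DESeq2, 819 and 1048 with library totals, and 752 and 964 with a GC and length offset. All 3 sh-ALYREF libraries lay on one side of all 3 sh-NC libraries for 28.8% of tested genes in HepG2 and 42.6% in Huh7, where chance gives 10%. UCHL1, a deubiquitinating enzyme (ENSG00000154277, chromosome 4, 41256928 to 41268455), rose 10.3-fold from 1.82 ± 0.399 to 18.8 ± 4.29 CPM (SD, n = 3, adjusted p = 1.06e-13). MAP3K20, a stress-activated kinase (ENSG00000091436, chromosome 2, 173075517 to 173268015), rose 4.66-fold from 6.37 ± 0.847 to 29.6 ± 2.42 CPM. SYNE2, a nuclear envelope protein (ENSG00000054654, chromosome 14, 63761596 to 64226449), rose 4.40-fold from 29.2 ± 2.96 to 128 ± 6.71 CPM. GNG12, a G protein gamma subunit (ENSG00000172380, chromosome 1, 67701475 to 67833467), fell 6.26-fold from 23.5 ± 0.957 to 3.76 ± 0.512 CPM (adjusted p = 2.26e-15). SLC2A1, the glucose transporter GLUT1 (ENSG00000117394, chromosome 1, 42925353 to 42958868), fell 2.35-fold from 610 ± 10.9 to 260 ± 16.6 CPM (adjusted p = 1.31e-13).

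The other named HepG2 rises were PTPRJ (log2 2.46), NECTIN3 (1.84), SPIRE1 (1.78), GALC (1.72), NRP1 (1.69), PIK3AP1 (1.56) and BRDT (1.56). The other falls were SLC25A27 (-2.22), MEP1A (-1.95), ALDH1L2 (-1.52), DDIT4 (-1.41), GRB10 (-1.16), BCAT1 (-1.16), DNAH17 (-1.13) and ADI1 (-1.0). DDIT4 inhibits mTORC1 and is induced by stress, and BCAT1 is the cytosolic branched-chain aminotransferase. The GALC call, at 0.243 against 0.868 CPM, ended without sh-ALYREF replicate 1 (1.13), sh-NC replicate 2 (1.35) or sh-NC replicate 3 (1.51), and its value was 2.58 without sh-NC replicate 1. That of ADI1 ended without sh-NC replicate 1 (-0.51) and under DESeq2 (-0.98), and those of GALC and BRDT in a fit of the 6 HepG2 libraries alone. In the sh-ALYREF libraries of HepG2, 112 genes that Huh7 expressed and HepG2 sh-NC nearly lacked stood at a median of 0.978%, 0.498% and 0.945% of their Huh7 level, against 0.423%, 0.576% and 0.514% in sh-NC. Since these genes were chosen as low in sh-NC, part of this contrast is built in. GALC (0.963%) and BRDT (1.2%) lay at a like share of their Huh7 level, PTPRJ (2.67%) and NRP1 (3.51%) a little above it, and UCHL1 (12.4%) and MAP3K20 (23.1%) well above it.

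Of 28 gene lists tested with camera, 14 passed in HepG2, and 9 of these also passed with an estimated correlation. Wrong groupings of the HepG2 libraries called at most 2 genes but up to 9 lists with the preset correlation. Each wrong grouping mixes the 2 hairpins unequally and so keeps part of any real effect. The number of lists it called is thus no rate of false calls. A list call may still be weaker evidence than its p value, since not every call held with an estimated correlation. Cholesterol synthesis genes rose most clearly: 20 of 25 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.54 (adjusted p = 3.17e-55, and 1.06e-04 with an estimated correlation). HMGCS1 rose by 1.11 (SE 0.0383), SQLE by 0.78 (SE 0.0414) and MSMO1 by 0.95 (SE 0.052). Among 39 secreted liver proteins, 25 rose and 0 fell (26 and 1 adjusted over the list alone; adjusted p = 1.47e-23, and 3.09e-04 with an estimated correlation). These included ALB, serum albumin (0.44), TTR, transthyretin (1.11), C3, complement component 3 (0.54), and FGA, a fibrinogen chain (0.47). Liver enzymes and transporters rose as a list (adjusted p = 1.76e-04, and 0.00695 with an estimated correlation), with 7 of 32 up and 0 down (8 and 0 adjusted over the list alone), among them SULT2A1 (0.72) and ALDH1A1 (0.38). NF-kB and inflammation genes had 6 of 23 up and 0 down (8 and 0 adjusted over the list alone; adjusted p = 4.42e-04, and 0.0256 with an estimated correlation), including SOD2 (0.52), CCL20 (0.40) and LCN2 (0.94). Fatty acid and triglyceride genes had 14 of 32 up and 3 down (15 and 4 adjusted over the list alone; adjusted p = 4.51e-05, and 0.0053 with an estimated correlation), including FABP1 (0.77), FADS2 (0.50) and SCD (0.29). The median (0.18) and the test of this last list pointed up, while its mean was -0.02.

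ATF4 and unfolded protein response genes fell in HepG2. Of 30, 15 fell and 2 rose (16 and 4 adjusted over the list alone; adjusted p = 3.74e-20, and 1.06e-04 with an estimated correlation). SLC7A11, the cystine transporter, fell by 0.66, PSAT1 and SHMT2, enzymes of serine and glycine synthesis, by 0.52 and 0.60, and DDIT4 by 1.41 on the log2 scale. Ribosome biogenesis and MYC targets had 15 of 31 down and 0 up (22 and 0 adjusted over the list alone; adjusted p = 2.66e-12, and 0.00394 with an estimated correlation), with DDX21 at -0.36 and ODC1 at -0.47. Hypoxia and glycolysis genes had 11 of 32 down and 2 up (13 and 5 adjusted over the list alone; adjusted p = 8.19e-07, and 0.00458 with an estimated correlation), with SLC2A1 at -1.23, PKM at -0.32, ENO1 at -0.29 and NDRG1, a rise, at 0.58. S phase genes fell by a small margin (median log2 -0.11, 3 of 35 down and 0 up, 2 and 0 adjusted over the list alone; adjusted p = 0.00206, and 0.0171 with an estimated correlation), with MCM7 at -0.32.

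A further 5 HepG2 lists passed with the preset correlation and not with an estimated one. Cytoplasmic ribosomal proteins had 35 of 70 down and 0 up (43 and 0 adjusted over the list alone; adjusted p = 3.28e-12, and 0.105 with an estimated correlation), with RPLP0 at -0.26 and RPSA at -0.28. Replication-dependent histones had 15 of 36 down and 1 up (19 and 2 adjusted over the list alone; adjusted p = 4.33e-06, and 0.105 with an estimated correlation). G2 and mitosis genes had 8 of 42 down and 0 up (12 and 0 adjusted over the list alone; adjusted p = 6.6e-04, and 0.105 with an estimated correlation), with TPX2 at -0.27. Fetal liver and hepatocellular carcinoma markers had 8 of 20 up and 2 down (10 and 4 adjusted over the list alone; adjusted p = 0.00444, and 0.123 with an estimated correlation), with AFP, alpha-fetoprotein, at 0.35 and DLK1 at -0.65. Immediate early genes had 7 of 23 up and 1 down (8 and 1 adjusted over the list alone; adjusted p = 0.0256, and 0.163 with an estimated correlation), with EGR1 at 1.07; without sh-ALYREF replicate 2 or sh-NC replicate 2 the adjusted p was 0.0887 or 0.0656. The 14 lists that did not pass in HepG2 had adjusted p from 0.0682 (TREX and mRNA export, 2 of 27 down and 0 up) to 0.721 (EGFR and STAT3 signalling, 6 of 39 up and 7 down). Fibroblast, endothelial and leukocyte markers were among these (adjusted p = 0.182).

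In Huh7 with sh-ALYREF, secreted liver proteins rose as a list, as in HepG2, though 8 of 39 fell, and Wnt and beta-catenin targets fell. Hypoxia and glycolysis genes rose and cholesterol synthesis genes fell, both opposite to HepG2, though the cholesterol call did not hold with an estimated correlation (0.0631). The test called 3810 of 13642 genes, with 2008 up and 1802 down (1832 and 2064 with a GC and length offset). CP, the copper carrier ceruloplasmin (ENSG00000047457, chromosome 3, 149162414 to 149221829), rose 4.52-fold from 121 ± 5.42 to 547 ± 5.35 CPM (SD, n = 3, adjusted p = 1.16e-19). PLG, plasminogen (ENSG00000122194, chromosome 6, 160702193 to 160754097), rose 3.42-fold from 69.8 ± 4.12 to 239 ± 14.04 CPM (adjusted p = 2.58e-14). DKK1, a secreted Wnt antagonist and Wnt target (ENSG00000107984, chromosome 10, 52314281 to 52317657), fell 3.94-fold from 124 ± 4.86 to 31.4 ± 3.01 CPM (adjusted p = 7.38e-19). LGR5, a receptor that strengthens Wnt signalling (ENSG00000139292, chromosome 12, 71439129 to 71586310), fell 2.72-fold from 41.3 ± 5.15 to 15.2 ± 0.621 CPM. CYP1A1, a xenobiotic-metabolising enzyme (ENSG00000140465, chromosome 15, 74719542 to 74725528), fell 2.25-fold from 160 ± 6.59 to 71.2 ± 6.41 CPM.

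The other named Huh7 rises were PTPRG (log2 2.36), EPDR1 (2.14), SLC6A8 (2.11), GABRE (2.10), TMEM45B (1.72), HIST1H4K (1.70), PIEZO2 (1.68) and DLK1 (1.63). The other falls were ANTXR1 (-2.15), MALRD1 (-1.97), TNFRSF19 (-1.58), ZNF114 (-1.57), CYR61 (-1.2), ARFGEF3 (-1.19) and DZIP1 (-1.14). HIST1H4K, 1 of several near-identical histone H4 genes, was uneven between replicates (36.7 ± 37.8 CPM in sh-NC). Its call ended under DESeq2, with a GC and length offset, and without sh-ALYREF replicate 1 (1.77) or 2 (1.56) or sh-NC replicate 1 (1.22) or 3 (1.45), and its value was 2.97 without sh-NC replicate 2. GABRE (0.198 against 0.883 CPM) and DLK1 (0.416 against 1.35 CPM) were near the floor in Huh7 and did not pass in a fit of the 6 Huh7 libraries alone.

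Camera called 10 of the 28 lists in Huh7, and 3 of them also passed with an estimated correlation. Wrong groupings of the Huh7 libraries called up to 7 lists with the preset correlation, which, as in HepG2, can hold part of a real effect. Wnt and beta-catenin targets fell: 12 of 18 fell and 0 rose, also when adjusted over the list alone (median log2 -0.41; adjusted p = 5.3e-12, and 0.00138 with an estimated correlation). They included DKK1 (-1.98), LGR5 (-1.44), MYC (-0.63) and TBX3 (-0.50). Secreted liver proteins had 19 of 39 up and 8 down (19 and 10 adjusted over the list alone; adjusted p = 5.3e-12, and 0.0047 with an estimated correlation), with C3 at 0.97, SERPINC1, antithrombin, at 1.56, PLG at 1.77 and SERPINA1, alpha-1-antitrypsin, at 1.01. Hypoxia and glycolysis genes had 14 of 32 up and 2 down (16 and 3 adjusted over the list alone; adjusted p = 8.66e-07, and 0.00706 with an estimated correlation), with P4HA1 at 0.95, NDRG1 at 1.07, LDHA at 0.46 and TPI1 at 0.53.

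The other 7 Huh7 calls were lost with an estimated correlation. Cholesterol synthesis genes had 13 of 25 down and 1 up (16 and 1 adjusted over the list alone; adjusted p = 1.3e-07, and 0.0631 with an estimated correlation), with FDFT1 at -0.51, STARD4 at -0.59, ACAT2 at -0.45 and HMGCS1 at -0.34. Cytoplasmic ribosomal proteins had 23 of 70 down and 0 up (23 and 1 adjusted over the list alone; adjusted p = 1.24e-05, and 0.334 with an estimated correlation), with RPL14 at -0.66 and RPL5 at -0.48. Heat shock genes had 7 of 13 down and 0 up (8 and 0 adjusted over the list alone; adjusted p = 5.57e-05, and 0.118 with an estimated correlation), with the chaperones HSPA8 at -0.47 and HSP90AA1 at -0.37. Immediate early genes had 8 of 23 down and 0 up, also when adjusted over the list alone (adjusted p = 2.19e-04, and 0.0721 with an estimated correlation), with CTGF at -1.07 and JUN at -0.70. Ribosome biogenesis and MYC targets had 15 of 31 down and 0 up, also when adjusted over the list alone (adjusted p = 2.19e-04, and 0.0721 with an estimated correlation), with NPM1 at -0.37. NF-kB and inflammation genes had 7 of 23 up and 2 down, also when adjusted over the list alone (adjusted p = 0.00617, and 0.0853 with an estimated correlation), with SOD2 at 1.09, LCN2 at 1.54 and SAA2 at 1.80. Replication-dependent histones had 9 of 36 up and 1 down (11 and 1 adjusted over the list alone; adjusted p = 0.0125, 0.362 with an estimated correlation and 0.5 with a GC and length offset). The remaining 18 lists had adjusted p from 0.0534 (mitochondrially encoded mRNAs, 5 of 13 up and 0 down) to 0.977 (EGFR and STAT3 signalling, 11 of 39 up and 11 down).

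**Figure D2:**
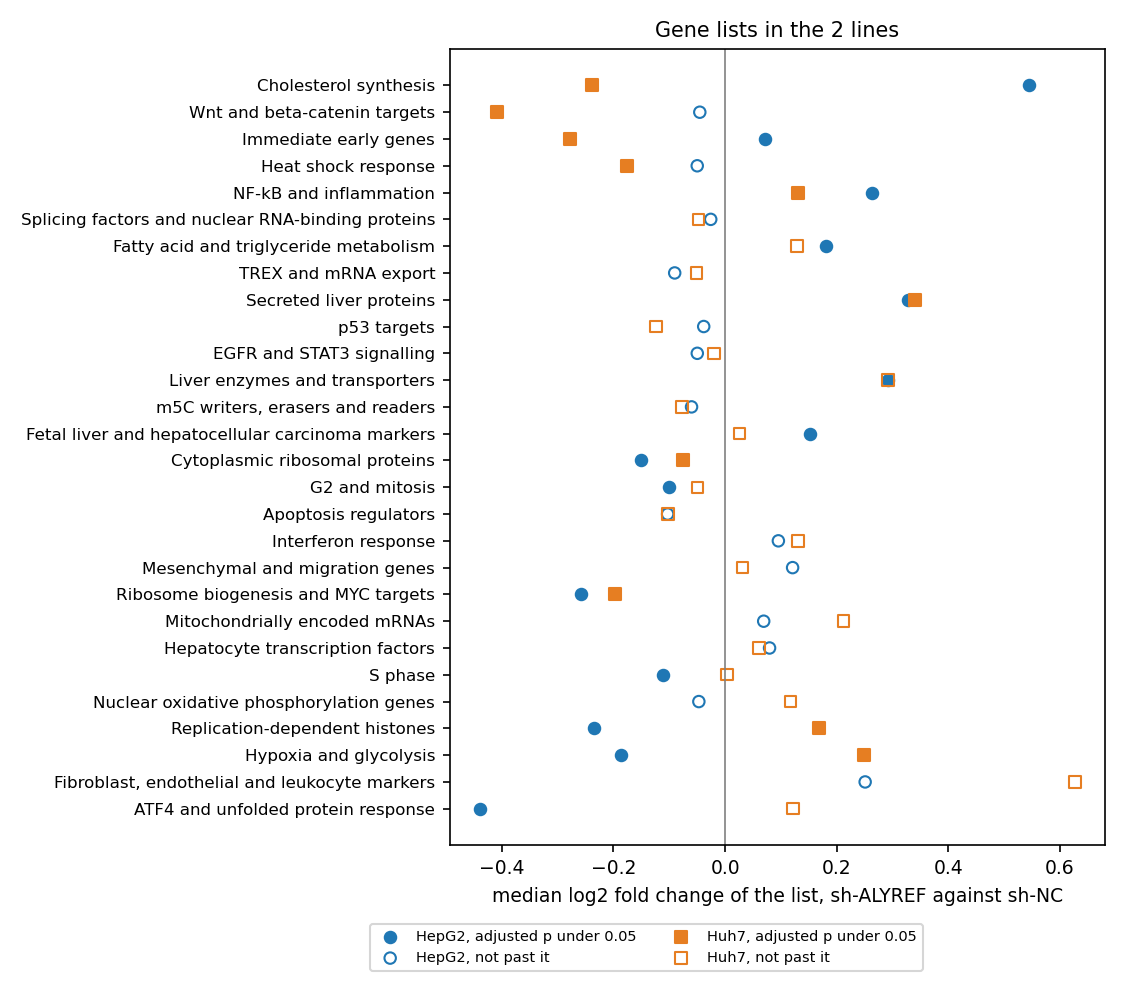
Median log2 fold change of each of the 28 gene lists, sh-ALYREF against sh-NC, in HepG2 (circles) and Huh7 (squares); filled symbols passed camera with the preset correlation. Cholesterol synthesis genes lay at 0.54 in HepG2 and -0.24 in Huh7, and secreted liver proteins at 0.33 and 0.34.

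The mean effect over both lines asked which genes changed on average, which includes genes that changed in 1 line alone. Secreted liver proteins rose, and ribosome biogenesis and MYC targets fell. The test called 3156 genes, of which 1725 rose and 1431 fell, against 1529 and 1785 with library totals and 1517 and 1928 with a GC and length offset. CP rose 3.06-fold (log2 1.61, SE 0.0364), SYNE2 2.62-fold (1.39, SE 0.0481) and PLG 2.53-fold (1.34, SE 0.0737). VCAN, the matrix proteoglycan versican (ENSG00000038427, chromosome 5, 83471744 to 83582302), fell 2.02-fold, from 607 ± 3.11 to 308 ± 20.8 CPM in HepG2 and from 151 ± 4.85 to 72.7 ± 8.72 CPM in Huh7. DKK1 fell by 1.16 on the log2 scale and GNG12 by 1.36. The other named rises were PTPRG (1.25), PIEZO2 (1.24), IRAK3 (1.23), NEB (1.21), SOX6 (1.2), FLRT3 (1.2) and GALC (1.16). The other named falls were CEMIP (-1.07), BCAT1 (-0.89), TNFRSF19 (-0.88), COLGALT2 (-0.79), NES (-0.79), TRNP1 (-0.60) and CHSY1 (-0.60). Of the genes named here, PTPRG (0.13), TNFRSF19 (-0.17), TRNP1 (-0.14) and CHSY1 (-0.19) did not pass in HepG2, nor GNG12 (-0.07) and CEMIP (-1.26) in Huh7. IRAK3 (1.38%), FLRT3 (1.59%) and GALC (0.963%) stood at under 2% of their Huh7 level in HepG2 sh-ALYREF. For their HepG2 rises, Huh7 RNA or reads in the HepG2 libraries stay a candidate explanation.

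Of the 28 lists, 12 passed for the mean effect, and 7 also passed with an estimated correlation. Secreted liver proteins rose as a list in both lines (mean effect, 24 of 39 up and 3 down, 25 and 4 adjusted over the list alone; adjusted p = 1.4e-27, and 4.39e-04 with an estimated correlation). Single members often differed between the lines: by the test of the difference, 11 of 39 were higher and 15 lower in HepG2. As a list they did not pass for the difference (camera adjusted p = 0.964). Ribosome biogenesis and MYC targets had 22 of 31 down and 0 up, also when adjusted over the list alone (adjusted p = 6.62e-12, and 0.00573 with an estimated correlation), with ODC1 at -0.50, NPM1 at -0.26, DDX21 at -0.30 and NOLC1 at -0.35. The other lists past both tests were Wnt and beta-catenin targets (down, 0.00214 as the p with an estimated correlation; not called in HepG2), fatty acid and triglyceride metabolism (up, 0.0118), ATF4 and unfolded protein response (down, 0.0183; 10 up and 4 down in Huh7), liver enzymes and transporters (up, 0.0183) and NF-kB and inflammation (up, 0.0203). Lost with an estimated correlation were cytoplasmic ribosomal proteins (down, adjusted p = 1.55e-13 against 0.11), cholesterol synthesis (up, 4.13e-06 against 0.0525), heat shock (down, 4.84e-04 against 0.155), G2 and mitosis (down, 0.00666 against 0.188) and mitochondrially encoded mRNAs (up, 0.0376 against 0.505). The mitochondrial call also ended with a GC and length offset (adjusted p = 0.106) and without any of 5 libraries, with adjusted p from 0.0711 (HepG2 sh-NC replicate 3) to 0.145 (Huh7 sh-ALYREF replicate 2); the others were HepG2 sh-NC replicate 2, Huh7 sh-ALYREF replicate 1 and Huh7 sh-NC replicate 2.

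The list of m5C writers, erasers and readers passed in no comparison (mean effect, 4 of 17 up and 5 down, adjusted p = 0.487). Among its members, YBX1, an m5C reader, fell by 0.29 and TRDMT1, a tRNA methyltransferase, by 0.66 on the log2 scale (adjusted p = 4.54e-06 and 8.03e-05). TREX and mRNA export genes (adjusted p = 0.0753), splicing factors and nuclear RNA-binding proteins (0.056) and p53 targets (0.174) did not pass for the mean effect. Neither did interferon response (0.143), hepatocyte transcription factors (0.334), mesenchymal and migration genes (0.471), nuclear oxidative phosphorylation genes (0.684) or apoptosis regulators (0.963). EGFR and STAT3 signalling, a list of the pathway named for this study and so not independent evidence, had 10 of 39 up and 9 down (11 and 11 adjusted over the list alone; adjusted p = 0.871). Its median (-0.06) and its test differed in sign, here and in HepG2, as did those of apoptosis regulators here. In Huh7, the signs of median, mean and test were mixed for apoptosis regulators and hepatocyte transcription factors. Mean and median also differed in sign for m5C writers, erasers and readers (-0.06 and 0.05) and for histones (0.03 and -0.05).

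The next question was where the effect of sh-ALYREF differed between the lines. Cholesterol synthesis, the ATF4 response, and hypoxia and glycolysis differed most clearly. A test of the difference (HepG2 effect minus Huh7 effect) called 2670 genes, with 1371 higher and 1299 lower in HepG2 (1195 and 1469 with library totals, 1200 and 1239 with a GC and length offset). UCHL1 (3.43, SE 0.187) and MAP3K20 (2.21, SE 0.124) rose in HepG2, with log2 changes of -0.06 and 0.01 in Huh7. MALRD1 (1.98, SE 0.108) fell in Huh7 and stood at 0.01 in HepG2. ARFGEF3 (1.85, SE 0.0761), a regulator of secretion, rose in HepG2 (0.66) and fell in Huh7 (-1.19). MEP1A, a membrane metalloprotease (-2.61, SE 0.136), and DDIT4 (-2.24, SE 0.161) fell in HepG2 (-1.95 and -1.41) and rose in Huh7 (0.66 and 0.83).

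Camera called 7 lists for the difference, and 5 also passed with an estimated correlation. Cholesterol synthesis had 20 of 25 genes higher in HepG2 and 1 lower, also when adjusted over the list alone (median difference 0.85; adjusted p = 2e-49, and 3.58e-04 with an estimated correlation). HMGCS1 changed by 1.11 in HepG2 and by -0.34 in Huh7, and SQLE by 0.78 and -0.31. ATF4 and unfolded protein response genes had 17 of 30 lower in HepG2 and 2 higher (adjusted p = 6.21e-14, and 3.58e-04 with an estimated correlation), and hypoxia and glycolysis genes 16 of 32 lower and 1 higher (adjusted p = 6.21e-14, and 5.25e-04 with an estimated correlation), both also when adjusted over the list alone. Wnt and beta-catenin targets had 9 of 18 higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 2.87e-10, and 6.83e-04 with an estimated correlation), and immediate early genes 10 of 23 higher and 1 lower, also when adjusted over the list alone (adjusted p = 1.01e-06, and 0.0227 with an estimated correlation). Histones had 15 of 36 lower and 0 higher (21 and 1 adjusted over the list alone; adjusted p = 1.57e-07, and 0.112 with an estimated correlation), and heat shock genes 5 of 13 higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.00273, and 0.287 with an estimated correlation). Lists whose median, mean and test differed in sign here did not pass.

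**Figure D3:**
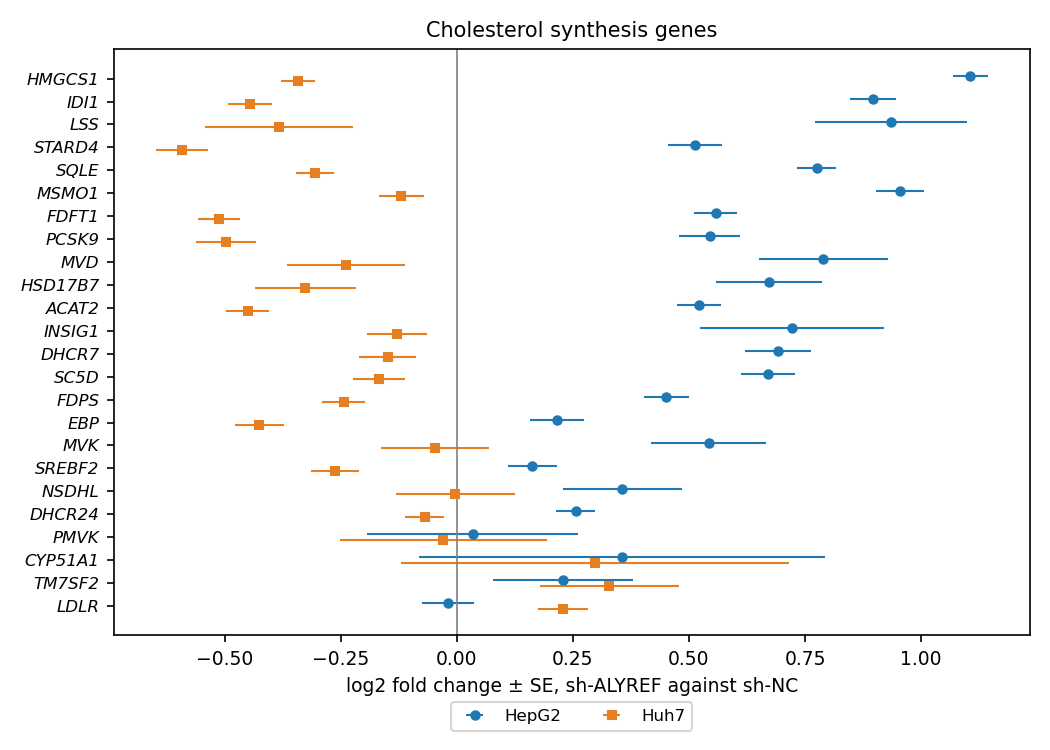
Log2 fold change with SE of 24 of the 25 tested cholesterol synthesis genes, sh-ALYREF against sh-NC, in HepG2 (circles) and Huh7 (squares), ordered by the difference between the lines. Of all 25, 20 rose in HepG2, and in Huh7 13 fell and 1 rose.

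Across genes, which are not independent replicates, the effects in the lines were nearly uncorrelated (Spearman rho 0.0618, Pearson r 0.0494, 13642 genes). Of 865 genes called in both lines, 526 changed in the same direction and 339 in opposite directions. Both lines shared 337 rises, where 150 were expected if every gene were equally likely to be called (Fisher's exact test, two-sided, adjusted p = 4.88e-53), and 189 falls, where 98.8 were expected (adjusted p = 1.08e-19). Genes that rose in HepG2 and fell in Huh7 (200, with 134.6 expected) and those that fell in HepG2 and rose in Huh7 (139, with 110.1 expected) also exceeded this expectation. Genes easily called in both lines raise every such overlap, so these p values do not measure agreement alone. The excess was larger for the same direction (2.25 and 1.91 times) than for opposite directions (1.49 and 1.26 times).

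Among 21002 tested lncRNA transcripts, 12985 of which overlap exons of a coding gene on the same strand, 35 changed in HepG2 (30 up, 5 down) and 75 in Huh7 (51 up, 24 down). AC007638.2 (ENST00000574716, chromosome 17, 55271504 to 55273653), an intronic antisense transcript, fell by 6.77 on the log2 scale in HepG2, from 384 ± 73.3 to 3.77 ± 5.05 CPM of lncRNA reads (SD, n = 3, adjusted p = 1.14e-09). AC105105.5 (ENST00000622635, chromosome 18, 58476191 to 58477484), an intergenic transcript, rose by 4.84 from 4.55 ± 3.43 to 134 ± 25.6 CPM. AC105105.1 on the same chromosome (58535415 to 58538552) rose by 3.82. In Huh7, AC087273.2 (chromosome 8, 17905756 to 17907887) rose by 4.44, from 3.43 ± 3.92 to 78.2 ± 32.3 CPM, and AL117339.4 (chromosome 10, 38137337 to 38144399) fell by 1.56, from 126 ± 21.1 to 42.7 ± 8.30 CPM. A transcript overlapping CP exons (ENST00000473296) rose by 4.35 in Huh7, and AL669831.5 fell by 1.5. The Huh7 transcript of the LGR5 locus (ENST00000547310) had 30 reads in sh-NC and 0 in sh-ALYREF, at least 8.31-fold lower against a floor of 3 reads over the group. LINC00920 had 2 and 50 reads in Huh7, a ratio of 30.1 (95% Clopper-Pearson interval 7.91 to 255). In HepG2, AP003900.1 had 1 and 26 reads (ratio 30.3, interval 4.98 to 1240), AC009948.1 had 47 and 2 (ratio 20.2, interval 5.28 to 171), and AC008109.1 fell by 3.74. Intervals and floors cover counting error only. DESeq2 called 85 and 230 transcripts, and the Huh7 count was 49 without sh-ALYREF replicate 1, 35 without sh-ALYREF replicate 2, 45 without sh-NC replicate 1 and 31 without sh-NC replicate 2; the HepG2 count was 22 without sh-ALYREF replicate 3 and 21 without sh-NC replicate 2. The calls of AC007638.2, AC105105.5, LINC00920 and AC087273.2 held without each library in turn, and those of the other named lncRNAs ended without at least 1 library. Examples are AC105105.1 (3.31) and AP003900.1 (3.99) without HepG2 sh-NC replicate 1, AC009948.1 (-3.59) and AC008109.1 (-3.70) without HepG2 sh-NC replicate 2, AL117339.4 (-1.39) and AL669831.5 (-1.38) without Huh7 sh-NC replicate 1, and the CP (3.79) and LGR5 (-5.55) transcripts without Huh7 sh-NC replicate 2. AC009948.1 reached -7.00 without HepG2 sh-ALYREF replicate 1.

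No circRNA passed the edgeR test in either line among 2547 tested (0 and 0 calls, smallest adjusted p 0.677 in HepG2 and 0.811 in Huh7), with 115 and 115 at an unadjusted p under 0.05 and 0 and 0 by DESeq2. The circRNAs with the smallest p, none past the threshold, were of LIFR (chromosome 5, 38523419 to 38530666), SHANK2, L3MBTL4, ANKIB1 and UTRN in HepG2 and of COBLL1, EMB, PTBP2, ATF2 and SHOC2 in Huh7. The LIFR circRNA had 42 junction reads in HepG2 sh-NC and 7 in sh-ALYREF. With a median of 1.33 junction reads per circRNA and library, few changes of even 4-fold were detectable: in simulated data of this depth, 0% of 4-fold changes in HepG2 and 2.04% in Huh7 were recovered.

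The m5C peaks addressed whether sh-ALYREF changed the mark itself. HepG2 lists held 22860 ± 5390 mRNA peaks in sh-NC and 15850 ± 5077 in sh-ALYREF (SD, n = 3; exact permutation test, two-sided, p = 0.3, log2 ratio -0.55). Huh7 lists held 19050 ± 2541 and 18820 ± 4661 (exact p = 0.9, log2 ratio -0.04). With 3 against 3, the smallest p possible is 0.1. Permuting within lines gave p = 0.175 for both lines together (exact, 400 assignments, smallest possible 0.005; log2 ratio -0.29) and p = 0.24 for the difference between lines. Every peak had a caller score of at least 50, but the caller's own FDR was nowhere below 25.1%, and the median FDR of the lists ran from 39.5% to 100%.

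**Figure D4:**
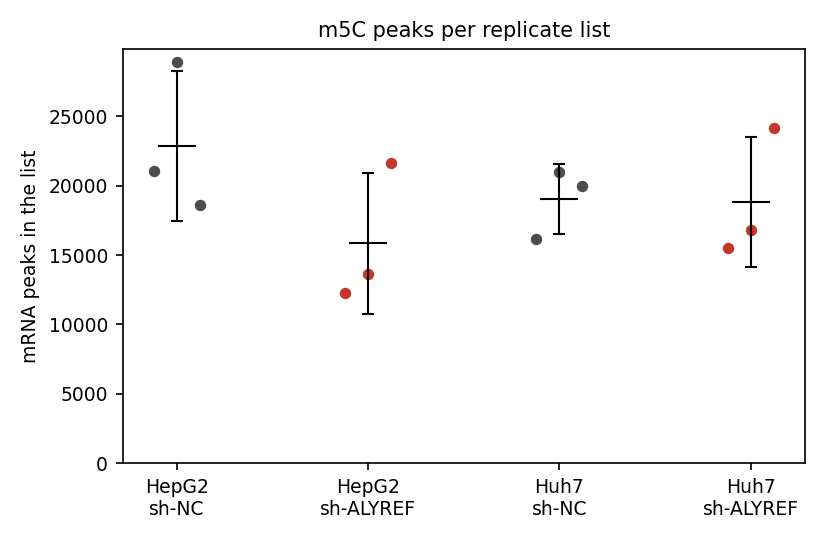
Number of mRNA m5C peaks in each replicate's list by group, with points for replicates, a line for the mean and bars for the SD (n = 3). Group means were 22860 and 15850 in HepG2 and 19050 and 18820 in Huh7, and the replicates of the groups overlapped.

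Overlapping peaks of a line were merged into 49750 regions in HepG2 and 42240 in Huh7. In HepG2, 3600 regions were in all 6 lists and 23685 in 1 list, and in Huh7 4634 and 16515. A region present in all 3 sh-NC lists and no sh-ALYREF list was counted as lost, and the reverse as gained. In HepG2, 688 regions were lost and 192 gained, while the other assignments of the 6 lists gave up to 680 regions of 3 against 0. With the same 12258 strongest peaks from each list, the HepG2 direction turned, with 192 lost and 381 gained (other assignments up to 336). In Huh7, 327 were lost and 260 gained, with up to 528 in the other assignments; with 15495 peaks from each list, 271 were lost and 269 gained (other assignments up to 258). Lists of the same group shared 33.8% of peaks in HepG2 and lists of different groups 31.3%, and in Huh7 39.2% and 38.6%.

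At the same place in both lines, 8 regions were lost and 2 gained; 6 of 324 pairs of other assignments gave as many as 8 and 146 as many as 2, with a median of 1 and a highest of 9. A further 6 places were lost in HepG2 and gained in Huh7, and 3 the reverse. Lost regions lay in the 5′ UTR of RDM1 (chromosome 17, 35930076 to 35930769), PTAFR (chromosome 1, 28193722 to 28193936) and RBPMS (chromosome 8, 30442617 to 30442800). Others, in coding sequence, included regions of OR2C1, CEP170B (chromosome 14, 104876256 to 104876345), EPHB2 and LAMC3. The gained regions lay in the 3′ UTR of DUSP13 (chromosome 10, 75094432 to 75094878) and the 5′ UTR of ZNF609 (chromosome 15, 64460742 to 64460838). The RDM1 region had an enrichment of 8.07 to 11.8-fold in the 3 HepG2 sh-NC lists and 9.24 to 16.04-fold in those of Huh7. EGFR carried 7.67 ± 2.31 peaks per list in HepG2 sh-NC and 5.0 ± 2.0 in sh-ALYREF, and 2.67 ± 0.577 and 1.0 ± 0 in Huh7 (SD, n = 3). These numbers were not tested. Over all mRNA peaks, the ratio of sh-ALYREF to sh-NC was 0.68 in HepG2 and 0.98 in Huh7, so the HepG2 fall on EGFR is not particular to this gene. The EGFR 5′ UTR region (chromosome 7, 55019021 to 55019365) was in 3 sh-NC and 0 sh-ALYREF lists in HepG2, and in 3 and 2 in Huh7. ALYREF had 1 peak in 1 of the 12 lists, and STAT3 1 peak in 4 of them.

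Peaks lay mostly in coding sequence (63.7% in sh-NC and 63.4% in sh-ALYREF over both lines), followed by the 5′ UTR (19.7% and 19.7%), the 3′ UTR (16.5% and 16.6%) and introns (0.217% and 0.224%). None of these shares passed over both lines (exact permutation within lines, two-sided, adjusted p = 0.965 for all 4). The share in coding sequence moved in opposite directions, from 64.0% to 63.0% in HepG2 (exact p = 0.4) and from 63.3% to 63.9% in Huh7. This Huh7 share and the HepG2 intron share (0.215% and 0.234%) separated fully, at the smallest exact p possible (0.1, n = 3 against 3). Peaks were more frequent on genes without input reads than on the most highly expressed genes. In HepG2, 48.3% of the 1406 genes without a read in the 6 input libraries carried a peak in an average list, and in Huh7 53.2% of 532. The share was 56.5% and 56.3% at 1 to 10 CPM and 28.6% and 23.8% over 100 CPM. The median GC content of these 3 classes took the same order, with 49.6%, 54.9% and 43.5% in HepG2.

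**Figure D5:**
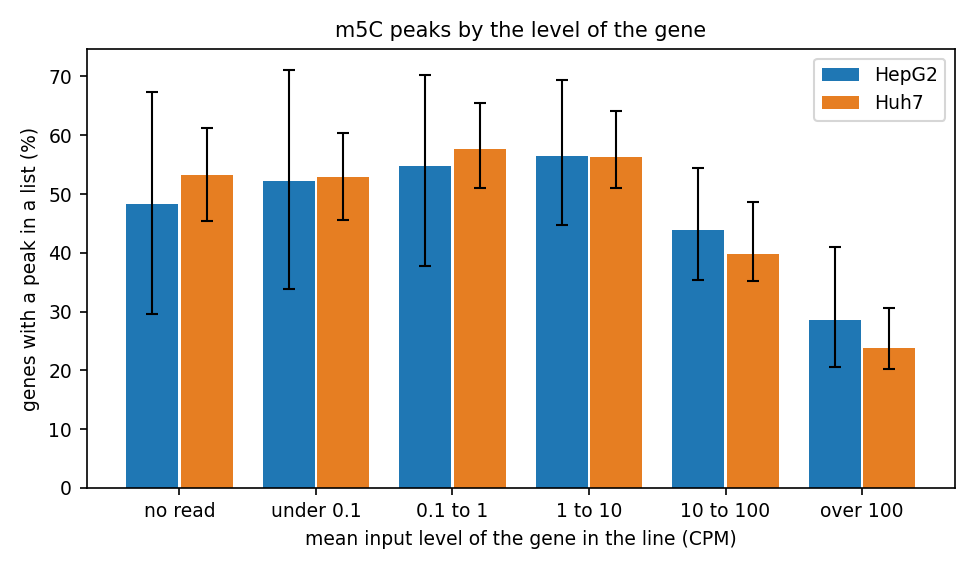
Share of genes with an m5C peak in an average list (%) by the mean input level of the gene in the line (CPM), in HepG2 and Huh7; bars are means of 6 lists and lines run from the lowest to the highest list. The share was 48.3% and 53.2% for genes without a read and 28.6% and 23.8% for genes over 100 CPM.

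The last comparison asked whether RNA levels changed where an m5C peak was lost. In HepG2, 411 genes with a lost region had a median log2 change of 0.0, against -0.02 in genes of like level with a peak in all 6 lists (permutation test over genes, p = 0.199, adjusted p = 0.404). In Huh7, 231 such genes had a median of 0.08 against 0.05 (permutation p = 0.202, adjusted p = 0.404). For genes with a gained region, 135 in HepG2 and 161 in Huh7, the medians were -0.03 and 0.05 against -0.03 and 0.04 (permutation p = 0.926 and 0.766). None of these 4 tests passed. Of the Huh7 genes with a lost region, 46 were called up and 14 down, and of those with a gained region 24 and 16, against 2008 and 1802 of all tested genes. In HepG2 the numbers were 19 and 12 for lost regions and 7 and 9 for gained ones, against 1019 and 748. These counts were not tested.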

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

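The test of the difference, its lists, the agreement between lines and the fits without each library for genes were planned, and the test on overlapping genes was set before its result was seen; the other splits and the other tests of explanations were chosen after.

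The effect of sh-ALYREF differed between HepG2 and Huh7 for 2670 genes by the test of the difference (HepG2 effect minus Huh7 effect, 3 libraries per group). The largest positive differences among the named genes, on the log2 scale, were UCHL1 (3.43), PTPRJ (2.38), ANTXR1 (2.30), MAP3K20 (2.21), NRP1 (2.10), MALRD1 (1.98), ARFGEF3 (1.85), NOTCH2 (1.70), GPR180 (1.65) and DKK1 (1.64). The negative ones were RBFOX2 (-2.70), MEP1A (-2.61), GNG12 (-2.57), SLC6A8 (-2.39), SLC25A27 (-2.35), DLK1 (-2.28), DDIT4 (-2.24), PTPRG (-2.23), EPDR1 (-2.04) and GABRE (-1.99). RBFOX2 was uneven in HepG2 sh-NC (43.99 ± 47.5 CPM; SD, n = 3), and its difference was -1.29 without HepG2 sh-NC replicate 3. The lists that differed were cholesterol synthesis (camera adjusted p = 2e-49), ATF4 and unfolded protein response (6.21e-14), hypoxia and glycolysis (6.21e-14), Wnt and beta-catenin targets (2.87e-10), histones (1.57e-07), immediate early genes (1.01e-06) and heat shock (0.00273). With an estimated correlation, the calls of histones (0.112) and heat shock (0.287) were lost.

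Other splits of the libraries tested chance; for the mean effect and the difference, 100 were drawn from the 200 ways to relabel both lines, including the exchange of labels in 1 line. For the difference, 2 of 100 splits gave as many genes, with 3156 the highest other, which is the mean effect reached by exchanging the labels in 1 line; for the mean effect 1 of 100 did (3156 genes, highest other 2670). These shares, under the threshold of 0.05 chosen after the data were seen, argue against chance in the assignment of libraries for both. They address the case of no effect in either line, and not that of an equal effect in both lines. The smallest share this test can give is 1 of 100. It cannot address a difference in culture between the groups of a line. For the agreement of effects between lines (0.0618) the share was also under 0.05 (4 of 100), but the highest other was 0.0685, and the value was 0.0404 without HepG2 sh-ALYREF replicate 1, so this result is weak. Chance is not excluded for the number of lists called for the mean effect (12, 6 of 100, highest other 13) or for the difference (7, 20 of 100, highest other 13) by these counts. All 6 splits as large for the mean effect and 18 of the 20 for the difference keep the labels of at least 1 line, exchanged or not, and so carry its effect. Where both lines were relabelled (82 splits), 0 and 2 gave as many lists, with 8 the highest for each. Within a line, 3 against 3 give 10 splits, too few for a share under 0.05. The real and highest other values were 1767 and 2 genes in HepG2 (1 split as large), 3810 and 0 in Huh7 (1), 14 and 9 lists in HepG2 (1), 10 and 7 in Huh7 (1), 35 and 2 lncRNA transcripts in HepG2 (1), 75 and 0 in Huh7 (1), and 0 and 0 circRNAs in both (10). For regions lost or gained they were 880 and 775 in HepG2 (1) and 587 and 633 in Huh7 (3).

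Many genes that rose at least 2-fold in HepG2 stood higher in Huh7 than in HepG2 sh-NC, 109 of 163 of them over 10 times. This ratio can also be high where the Huh7 level is low. Huh7 RNA or reads in the HepG2 sh-ALYREF libraries would raise genes that stand far higher in Huh7. After each library's share of the other line's signal was subtracted, 83.4% of the 163 were still called. Subtraction raised some folds, so a kept call alone is weak evidence. The 140 rises above 2% of their Huh7 level, of which 127 stayed called, stand above that share by definition (upper quartile at most 1.51% in HepG2 sh-ALYREF). For genes far above it, such as UCHL1 and MAP3K20 at 12.4% and 23.1%, the level argues against foreign signal as the only source, if its share is alike for every gene. For those just above 2%, such as FHOD3 (2.28%) and PTPRJ (2.67%), it does not decide this, since the share varied between genes. For the 23 genes at no more than 2% of the Huh7 level, foreign signal stays a candidate explanation, beside a rise in HepG2 itself. Their level in sh-ALYREF replicate 2 was 0.563 of that in replicates 1 and 3 (median), near the 0.539 of the genes that HepG2 sh-NC nearly lacks and below the 0.936 of the other 140 rises; since 11 of the 23 are among the genes that HepG2 sh-NC nearly lacks, the 12 others are the fairer set, with 0.68 (quartiles 0.408 and 0.939), less clear. Subtraction does not decide it for these genes: 14 of the 23 calls were lost, but the fitted fold rose in 10 of the 14 and in 19 of all 23.

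Cholesterol synthesis genes moved apart between the lines, with 21 of 25 called for the difference and a median of 0.85. With an offset for GC content and length, 20 remained (median 0.89), and with the other line's signal subtracted 20 (median 0.87). Without each library in turn, the lowest count was 19, without HepG2 sh-NC replicate 1. These values argue against GC content and length, foreign signal or 1 deviating library as the cause of the whole pattern. A line-specific response to sh-ALYREF, and a difference in culture between the groups of a line, which the labels do not describe, were not tested.

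Of 1938 genes without an input read, counted per line, 49.6% carried an m5C peak in an average list. Reads from an overlapping gene are argued against as the main source, since the 880 without an overlap carried peaks as often (ratio 0.9939, a test set before its result was seen). Signal that does not depend on the gene's own RNA stays a candidate explanation: 124 genes expressed in 1 line and nearly silent in the other carried a peak at 54.0% in the line with the RNA and 51.9% in the other (ratio 1.041). GC content may contribute. In another set, of 1874 genes under 0.1 CPM in both lines, the top class of GC content carried peaks 2.606 times as often as the bottom class, with classes of equal size. For 7992 genes over 10 CPM in both lines the ratio was 3.32, so it is not particular to silent genes. DNA in the IP and gaps in the input were not tested, nor was a biological explanation.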

How the results depend on the processing

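Library totals without TMM, the GC and length offset, subtraction of the other line's signal, and, for the lists and the agreement between lines, other size factors, no filter (agreement alone) and leaving out libraries were chosen after the data were seen; the other alternatives were planned before the data were examined. Over 291 alternatives of the comparisons, 240 left the result as it was, 40 moved it and 11 reversed it. Over 10394 for single genes, lists and RNAs, 9813 left the result, 576 ended a call (354 of them through the 2-fold minimum), 5 added one and 0 reversed one. The 2-fold minimum cut the called genes by its construction to 243 in HepG2, 440 in Huh7, 261 for the mean effect and 472 for the difference. Of 43 list calls, 24 stood with an estimated correlation, and fry gave 76. LncRNA calls were 85 in HepG2 and 230 in Huh7 with DESeq2 and 80 and 129 without a filter; the cause was not tested. With equal list lengths, HepG2 lost 192 and gained 381 regions. The 5′ UTR share changed by -0.0715 points at a score of at least 70, and the difference for Huh7 genes with a gained region by -0.0281 with an overlap of at least 0.5 of both peaks, both reversed; neither passed its test in either setting, and the cause was not tested.

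Without each library in turn, called lncRNA transcripts ran from 21 (without HepG2 sh-NC replicate 2) to 37 in HepG2 and from 31 (without Huh7 sh-NC replicate 2) to 87 in Huh7. Others that moved a count over 1.5 times were HepG2 sh-ALYREF replicate 3 (22) and, in Huh7, sh-ALYREF replicates 1 (49) and 2 (35) and sh-NC replicate 1 (45). Shares by place, in points, ran from -0.383 to 0.547 for the 5′ UTR, -0.166 to 0.356 for the 3′ UTR and -0.569 to 0.101 for coding sequence. Lost regions ran from 910 to 2167 in HepG2 and 571 to 1081 in Huh7, gained ones from 362 to 590 and 406 to 973, since fewer lists are required when 1 is left out. Called genes ran from 1253 to 1745 in HepG2, 3155 to 3988 in Huh7, 2753 to 3051 for the mean effect and 2295 to 2705 for the difference, and list calls from 42 to 48. The log2 ratio of peak numbers ran from -0.42 to -0.20, and the correlation between lines from 0.0404 to 0.0706; with the GC and length offset that correlation was 0.104. With a replicate block, 1550 genes were called in HepG2, 3575 in Huh7, 2929 for the mean effect and 2482 for the difference. Pseudocount alternatives were not run, since the tables hold counts. Depth limits the lncRNA and circRNA tests (median 17.25 and 1.33 reads), and unknown IP depth limits every comparison of peak numbers.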

Other observations

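The KEGG pathways were chosen and tested after the data had been seen.

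Of 236 KEGG pathways of 15 to 300 genes, camera called 24 in HepG2, 11 in Huh7, 22 for the mean effect and 4 for the difference, and 10, 1, 9 and 1 of these also passed with an estimated correlation. Complement and coagulation cascades had 32 of 58 genes up and 2 down for the mean effect (adjusted p = 3.82e-20, and 5.82e-04 with an estimated correlation). Aminoacyl-tRNA biosynthesis had 2 of 43 up and 20 down (1.94e-06 and 0.0418), RNA transport 5 of 153 up and 58 down (1.94e-06 and 0.0418), and xenobiotic metabolism by cytochrome P450 18 of 48 up and 2 down (5.74e-05 and 0.0282). Butanoate metabolism had 11 of 24 up and 1 down (1.94e-06 and 0.0282), and steroid hormone biosynthesis 10 of 42 up and 1 down (0.00117 and 0.0418). For the difference, terpenoid backbone biosynthesis, the first part of cholesterol synthesis, had 8 of 21 higher in HepG2 and 1 lower (2.32e-12 and 0.00671).

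With each library's share of the other line's signal subtracted, 1663 genes were called in HepG2 (1632 of them among the 1767), 3714 in Huh7, 3000 for the mean effect and 2610 for the difference. EGFR stood at 0.68 in HepG2 (SE 0.134, adjusted p = 0.0014) and 0.40 in Huh7 (adjusted p = 4.99e-04), and ALYREF at -0.36 (adjusted p = 0.129) and -0.50 (adjusted p = 0.0231). All 14 HepG2 and 10 Huh7 lists called before were also called then.

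Per list, lncRNA peaks (log2 ratio -0.29, exact permutation p = 0.22), circRNA peaks (-0.49, p = 0.13), genes with a peak (-0.20, p = 0.165) and mRNA peaks with a score of at least 70 (-0.34, p = 0.15) were lower on average with sh-ALYREF over both lines, and none passed. Pairing the lists by replicate number gave an exact permutation p of 0.281 for mRNA peaks (64 assignments).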
